A study of Homo sapiens with 10 samples.

How the data were processed

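H4R3me2s was measured by ChIP-seq in 9 libraries of SH-SY5Y cells, 3 Naive, 3 BDNF and 3 BDNF+Dox, and 1 Input library from the same line served as background. Cells were grown with 10% FCS and 300 µg/ml zeocin and fixed with 1% formaldehyde for 10 minutes. Differentiation took 10 days, with 10 µM retinoic acid in 3% FCS for 6 days and 50 ng/ml BDNF without serum for 4 days, and doxycycline was given at 1 µg/ml for 3 days. Groups and replicate numbers were taken from the labels.

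Per the submitters' processing notes, reads were trimmed with cutadapt 1.1 and Trimmomatic 0.32, aligned to GRCh38 with Bowtie (version not stated), and peaks were called with MACS2 2.2.7.1. Per the file headers, each library was called against the Input as narrow peaks at a p threshold of 0.01. BDNF+Dox was also called over BDNF and over Naive, from 1 merged file per group, as narrow peaks and as broad peaks with a broad cutoff of 0.01. Per the file headers, 1 read was kept per position, the larger dataset was scaled to the smaller, local background windows were 1000 and 10000 bp, and the effective genome was 2.7e+09 bp. In the deposited files each peak has its length in bp, the pileup height, the −log10 p-value, the −log10 q-value and the fold enrichment, a ratio of treatment over local background, all computed by the authors with MACS2. The file headers state that q-values would not be calculated, whereas the deposited q column holds values, which were used as given. Coordinates in the deposited files start from 1. The calls test only for more signal in the treatment, so lists of the reverse direction were not used here, and a pooled list carries no spread between replicates. Folds and q-values were used only within their own list.

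Depth was read from the file headers, per which the 9 libraries kept between 17164402 and 18928589 reads and the Input 17074000, with fragment lengths between 151 and 178 bp. The merged groups held 55440136 (Naive), 54605625 (BDNF) and 57405446 (BDNF+Dox) reads, which equal the sums of their libraries. Peak lists hold no read counts per region, so no interval for a single peak was computed.

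The available gene annotation of GRCh38 held gene spans without strand, exons or assembly gaps. Promoters, planned as 2 kb around the transcription start, were therefore replaced by 2 kb around either end of a protein-coding gene (called gene ends), and gene body with 2 kb upstream by gene body with 2 kb on each side. Exons and introns were not told apart. Usable length was counted in bins of 1 Mb that hold a gene or a peak (2902 bins). Peaks were assigned to gene ends first, then to gene interiors. Unplaced contigs and mitochondrial DNA were left out of tests of location, genes, regions and chromosomes.

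Peak number and covered length (on the log10 scale), gene-end share and gene body share per library were compared by an exact permutation test of the F ratio over all 1680 assignments of the 9 libraries to 3 groups, and each pair of groups by an exact two-sided permutation test of the difference of means, whose smallest p is 0.1. Adjusted values are Benjamini-Hochberg over these 4 measures. Replicate overlap was the mean Jaccard index within groups minus that between groups, over all 280 partitions. Peaks overlapping by 1 bp or more were merged into regions, and regions with a peak in all 3 libraries of a group and none of another were counted and set beside the same count in the other splits of the libraries. For 3 libraries against 3, chance alone separates 10% of features without ties.

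Pooled peaks were placed at random 1000 times on their own chromosome within usable length (two-sided), and each of 18 gene lists fixed before the data were examined was compared with 10000 random lists of protein-coding genes matched on length in 20 bins (two-sided), with Benjamini-Hochberg adjustment over the lists. The lists were neuronal adhesion, synapse, axon and cytoskeleton, axon guidance, retinoic acid response, HOX, BDNF and immediate early response, noradrenergic and mesenchymal neuroblastoma markers, other cell types, BAF complex, arginine methyltransferases and partners, synuclein and Parkinson disease, histones, cell cycle, protocadherins, ribosome and splicing, and zinc finger genes. The background was all 19970 protein-coding genes. A result was called at a p or adjusted p under 0.05.

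The genes named from each pooled narrow list were, by a rule fixed before the data were examined, the 10 with the strongest gene-end peaks by q, the 10 with the strongest interior peaks, up to 10 list members with the strongest peaks, and always L1CAM and PRMT5, with some results of this rule not reported here. From the libraries they were genes with a gene-end peak in all 3 libraries of a group and none of the compared group, and genes with one in all 9. Genes named outside this rule were chosen after their values were seen: NMNAT2, OR10D3, VSTM2A, GABRA4, ANGEL2, HDAC9, MSI2, ALK, PRKCA and PRKCE, and members of lists at added thresholds.

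Alternatives fixed beforehand were a −log10 q of 3 or more, equal peak numbers per library (4536), leaving out each library, permutation within replicate numbers, primary chromosomes only, gene-end windows of 1 and 5 kb, other overlap rules, peaks widened by 500 bp, broad lists, pooled peaks seen in 2 or more BDNF+Dox libraries, gene ends only, and no length matching. Chosen after seeing the data were a −log10 p of 5 or more, a q of 0.05 or less, leaving out each library at a −log10 q of 3 or more, gene body share, list counts over gene bodies at library level, the hypergeometric tests of pooled against library peaks per gene (genes with at least 10 pooled and library peaks together) and per list, and the same test within chromosome segments. Computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 11.

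The procedures were tested on simulated data. With peak density raised 4 times, the gene-wise test called 35 of 59 altered genes and 0 others, with density raised 2 times it called 0 of 56, and with no change 0. The list test found the planted list, of which 15 of 31 genes were given a peak, and 0 others. The region count recovered 50 of 50 planted regions. These were placed identically in every list of a group, so their recovery was fixed by construction. Simulated peaks were otherwise scattered evenly, so false calls under coverage that varies along chromosomes were not checked. Peak calling was also simulated on unchanged groups at the measured depth, with even coverage over 2.7e+08 bp. Scaled up to the effective genome, this gave 4120 and 4160 calls per genome in the pooled comparisons and 3080 per library.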

Results

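Chromatin immunoprecipitation and sequencing (ChIP-seq) measured H4R3me2s, the symmetric dimethylation of arginine 3 of histone H4, in SH-SY5Y, a human neuroblastoma line that takes on neuronal traits under retinoic acid. PRMT5 is the main enzyme known to write this mark. The Naive group (n = 3) was not differentiated. The BDNF group (n = 3) received 10 µM retinoic acid for 6 days and then 50 ng/ml of the neurotrophin BDNF for 4 days. The BDNF+Dox group (n = 3) additionally received 1 µg/ml doxycycline for 3 days, which switched on α-synuclein from a Tet-on construct. A single Input library without antibody served as the control for all 9 ChIP libraries. After duplicates were removed the 9 libraries kept between 17164402 and 18928589 reads and the Input 17074000. Depth differed little between groups, at 18339700 ± 510271 (SD, n = 3) reads in BDNF+Dox, 17659100 ± 536562 in BDNF and 17925000 ± 192826 in Naive. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No group with doxycycline but without the α-synuclein construct was analysed here, and the effects of the drug and of the protein are therefore not separated.

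The comparison of BDNF+Dox with BDNF addressed whether induced α-synuclein changes where H4R3me2s lies in differentiated cells. NRCAM, a neuronal adhesion molecule of the L1 family on chromosome 7, held a region from 108322116 to 108322426 (GRCh38) with a peak in 3 of 3 BDNF+Dox libraries and in 0 of 3 BDNF and 0 of 3 Naive libraries. Over the whole gene, from 108147649 to 108456720, peaks numbered 3.67 ± 2.08 (SD, n = 3) per BDNF+Dox library, 1 ± 1 per BDNF library and 1 ± 1 per Naive library. A region from 124178589 to 124178936 on chromosome 11, 4.41 kb from the olfactory receptor gene OR10D3 and outside any annotated gene, was the only other region with peaks in all BDNF+Dox and no BDNF libraries. No region had peaks in all BDNF and no BDNF+Dox libraries. At gene ends, OR13G1, an olfactory receptor gene at 247670812 to 247679739 of chromosome 1, had a peak within 2 kb of an end in 3 of 3 BDNF libraries and in 0 of 3 libraries of either other group, and no gene showed the opposite pattern. The OR13G1 peaks did not share 1 place, since 0 regions had a peak in all 3 BDNF libraries. The number of NRCAM peaks did not differ beyond the spread between libraries (exact two-sided permutation p = 0.107 over the 3 groups and 0.2 for BDNF+Dox against BDNF). A single region cannot be called with 3 libraries against 3, because no exact test of such groups goes below 0.1, and other ways of splitting these 6 libraries gave up to 3 such regions where 2 were found. With equal peak numbers per library, or at a −log10 p of 5 or more, no region, that in NRCAM included, met the rule.

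**Figure D1:**
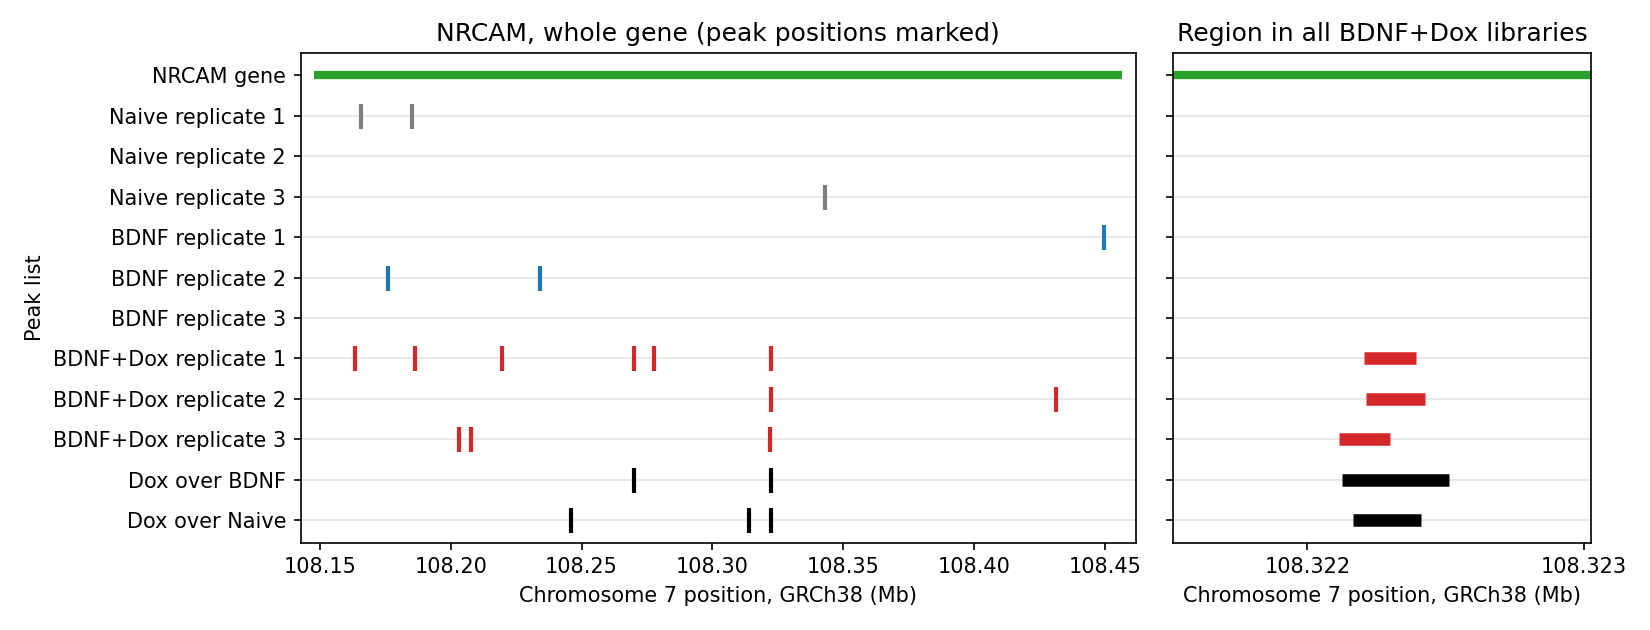
Peak positions across NRCAM on chromosome 7 (horizontal axis, Mb) in the 9 libraries and in both pooled lists (one line each on the vertical axis), with the whole gene at left and the shared region at right. All 3 BDNF+Dox libraries and both pooled lists have a peak between 108322116 and 108322514, where no Naive or BDNF library has one. The pooled lists were called from the reads of the same libraries.

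The authors also merged the 3 libraries of each group and called peaks of BDNF+Dox over BDNF directly. This narrow list held 9877 peaks, 9850 of them on chromosomes 1 to 22 and X, with a median fold of 2.77 in the authors' deposited table (folds and q-values per peak are the authors' own). RNF115, a ubiquitin ligase gene on chromosome 1, carried the strongest peak inside a protein-coding gene, at 145815113 to 145815349 with a fold of 5.31 and q = 7.19e-06 in the authors' deposited table. NRCAM followed in the authors' deposited table with a fold of 4.21 and q = 0.000243 at 108322126 to 108322514, the stretch that held a peak in all BDNF+Dox libraries. The merged reads are those of the same libraries, so the pooled NRCAM peak is not a second line of evidence. The next interior peaks by q in the authors' deposited table lay in NME7, GALNT17, GOLT1A, ROBO2, SND1, ABL2, TRANK1 and CSMD1, with q from 0.000367 in NME7 to 0.0212 in CSMD1 and folds from 3.56 in SND1 to 4.42 in GALNT17. Of these genes, ROBO2 encodes an axon guidance receptor. The peaks in RNF115, NME7, GALNT17 and ROBO2 overlapped a peak of 1 BDNF+Dox library. Those in GOLT1A, SND1, ABL2, TRANK1 and CSMD1 overlapped a peak of 0. Among gene ends, the authors' deposited table had q of 0.0108 at UPP1, 0.0262 at MAD2L1 (a spindle checkpoint gene), 0.0347 at BLVRA and 0.0455 at the histone gene H3-3B. The remaining gene ends of the 10 with the smallest q, namely GAP43, NGFR, SLC26A2, ZNF584, ZNF66 and IL7R, had q between 0.0757 and 0.113 in the authors' deposited table. The gene-end peaks at UPP1, BLVRA, ZNF66 and IL7R overlapped a peak of 1 BDNF+Dox library, and the others of 0.

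Most of this pooled list was weak. In the authors' deposited table, 94 of the 9877 peaks had q of 0.05 or less and 68.4% had q = 1. Of the 9850 peaks, 1766 (17.9%) overlapped a peak of at least 1 BDNF+Dox library and 57 a peak of 2 or more. L1CAM (chromosome X, 153861514 to 153886173), the namesake of the NRCAM family, and PRMT5 (chromosome 14, 22920529 to 22929376) had 0 narrow and 0 broad peaks in this comparison and 0 peaks in each of the 9 libraries. Both genes are much shorter than NRCAM and catch few peaks by chance, so these counts are no contrast to it.

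Genes of neuronal adhesion and of the axon made up most of the fixed-list members with strong pooled peaks over BDNF. NRCAM, ROBO2 and CNTNAP2 (a cell adhesion molecule of axons, q = 0.0477) represented adhesion in the authors' deposited table at q of 0.05 or less, MAPT, which encodes tau, had q = 0.0347, and the semaphorin gene SEMA6D had q = 0.0455. The growth cone gene GAP43 and the neurotrophin receptor gene NGFR (both q = 0.0757), the presynaptic gene RIMS2 (0.0745), the auxilin gene DNAJC6 (0.0877) and the adhesion gene NCAM2 (0.09) did not pass that threshold in the authors' deposited table. A narrow peak in the gene or within 2 kb of it was present in 22 of 29 adhesion genes, against 18.6 ± 2.28 (SD) in 10000 random lists of equally long genes, which was no excess (permutation p = 0.188, adjusted over the 18 lists 0.848). Axon and cytoskeleton genes had 11 of 21 against 5.91 ± 1.79 (p = 0.0118, adjusted 0.106) and markers of mesenchymal neuroblastoma cells 10 of 19 against 5.64 ± 1.63 (p = 0.0198, adjusted 0.119, two-sided permutation tests throughout).

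Protocadherins, clustered adhesion genes on chromosome 5, were the only fixed list past the threshold over BDNF, with 21 of 35 genes against 9.80 ± 2.34 (adjusted permutation p = 0.0072). The 21 genes share overlapping spans, however, and the count came from 3 distinct peaks between 140945573 and 141448416, each with q = 1 in the authors' deposited table. Library peaks in the cluster predicted 2.81 pooled peaks (exact two-sided hypergeometric p = 1). None of the remaining lists departed from length-matched lists over BDNF, with peaks in 13 of 29 synaptic genes (expected 11.5), 14 of 26 axon guidance genes (15.2), 5 of 21 retinoic acid response genes (3.65) and 1 of 39 HOX genes (0.939). Peaks lay in 4 of 27 BDNF and immediate early genes (2.54), 3 of 24 noradrenergic markers (2.42) and 1 of 24 markers of other cell types (2.16). Chromatin and disease lists had peaks in 8 of 29 BAF complex genes (6.27), 4 of 18 arginine methyltransferase and partner genes (2.47), 4 of 21 synuclein and Parkinson genes (4.06) and 0 of 33 histone genes (0.441). The last lists had peaks in 4 of 31 cell cycle genes (2.75), 0 of 30 ribosome and splicing genes (1.33) and 5 of 35 zinc finger genes (4.25). The adjusted permutation p was from 0.975 to 1 in these lists.

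At a stricter peak threshold chosen after seeing the data, −log10 p of 5 or more, the adhesion list stood out: 13 of 29 genes had a peak over BDNF against 4.76 ± 1.92 (adjusted permutation p = 0.0144), among them NRCAM, ROBO2, CNTNAP2 and NCAM2, and NLGN1 and LRRC4C, which were chosen after their values were seen. At q of 0.05 or less, 3 genes against 0.209 also passed (adjusted permutation p = 0.0288). The libraries called against Input held 67 peaks in the same genes at that −log10 p, which predicted 11.7 pooled peaks where 16 were found (exact two-sided hypergeometric p = 0.238). Matching in bins leaves length differences among the genes of a bin, and against library peaks no excess was shown.

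The comparison of BDNF+Dox with Naive combined differentiation and induction. In its narrow list of 7919 peaks (7882 on chromosomes 1 to 22 and X), 95 had q of 0.05 or less and 82.5% had q = 1 in the authors' deposited table. MECOM, a transcription factor gene, led the interior peaks with a fold of 4.48 and q = 0.000452 in the authors' deposited table. C1QTNF3, CDC25A (a cell cycle phosphatase), FAM72D, SND1, SPATS2, BAIAP2L1, MACROD2, AUTS2 and YY1AP1 followed in the authors' deposited table with q up to 0.00534. Among these interior peaks, those in CDC25A and SPATS2 overlapped a peak of 1 BDNF+Dox library, and the rest, MECOM included, of 0. Of the 7882 peaks, 1444 (18.3%) overlapped a peak of at least 1 such library and 41 a peak of 2 or more. At gene ends, GAGE2A had q = 0.000484 in the authors' deposited table, followed by CEP112 (0.0131), UTS2R (0.0144), BLVRA (0.0472) and then BTG2, GAP43, N4BP2, NGFR, SMS and ZNF66, all with q = 0.0593. The peaks at GAGE2A and CEP112 overlapped a peak of 0 BDNF+Dox libraries, and those at UTS2R and BLVRA of 1. Of the fixed-list members only NRCAM passed q of 0.05 in the authors' deposited table (fold 3.25, q = 0.0221). DNAJC6, DPYSL3 and SLIT3 had q = 0.0593, ROBO2 0.131, and RIMS2 and SEMA6D 0.164 in the authors' deposited table.

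NRCAM, SND1, BLVRA and ANGEL2 were the 4 protein-coding genes with a peak at q of 0.05 or less in both pooled comparisons, out of 24 such genes over BDNF and 38 over Naive (ANGEL2 was chosen after its values were seen). The SND1 peak overlapped a peak of 0 BDNF+Dox libraries in either list. In all, 2950 of the 9850 peaks over BDNF (29.9%) overlapped a peak over Naive, against 11.9 peaks with random placement (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Both comparisons use the same merged BDNF+Dox reads, however, and simulated calls on unchanged groups sharing those reads overlapped by 45.1%, more than the 29.9% found. The excess over random placement is therefore no evidence of a change shared by both comparisons.

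Fixed gene lists showed no departure over Naive. Peaks lay in or near 21 of 29 adhesion genes (expected 16.4), 12 of 29 synaptic genes (10.1), 8 of 21 axon and cytoskeleton genes (5.26) and 11 of 26 axon guidance genes (13.2). They lay in or near 3 of 21 retinoic acid response genes (3.23), 1 of 39 HOX genes (0.905), 4 of 27 BDNF and immediate early genes (2.27), 3 of 24 noradrenergic markers (2.22) and 5 of 19 mesenchymal markers (4.89). For the other lists the counts were 2 of 24 markers of other cell types (1.91), 7 of 29 BAF genes (5.52), 3 of 18 methyltransferase and partner genes (2.26), 4 of 21 Parkinson genes (3.57) and 0 of 33 histone genes (0.416). Peaks were found in 1 of 31 cell cycle genes (2.45), 9 of 35 protocadherins (8.22), 0 of 30 ribosome and splicing genes (1.12) and 6 of 35 zinc finger genes (3.89). Every adjusted permutation p was 1, and the smallest unadjusted p, for adhesion genes, was 0.089. At −log10 p of 5 or more, 10 adhesion genes against 3.95 ± 1.79 and 5 axon and cytoskeleton genes (GAP43, DPYSL3, and, chosen after their values were seen, ANK2, DPYSL2 and MAP2) against 0.945 ± 0.918 did pass (both adjusted permutation p = 0.0486). Library peaks in these adhesion and axon genes predicted 9.46 and 1.17 pooled peaks, and 14 and 5 were found (exact two-sided hypergeometric p adjusted over the lists 0.611 and 0.118).

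AUTS2, a neurodevelopmental gene on chromosome 7, and 5 genes chosen after their values were seen held more pooled peaks than their library peaks predicted, in a test chosen after seeing the data. Over BDNF these were AUTS2 (19 peaks against 5.75, exact two-sided hypergeometric p adjusted over 729 genes 0.00129), the deacetylase gene HDAC9 (16 against 5.11, 0.0107) and the RNA-binding protein gene MSI2 (8 against 1.66, 0.0242). Over Naive they were the receptor kinase gene ALK (12 against 2.41, adjusted over 690 genes 0.00107) and the protein kinase C genes PRKCA (12 against 2.83, 0.0046) and PRKCE (10 against 2.2, 0.00866). No gene passed in both comparisons, although both use the same BDNF+Dox reads. Against predictions from their own chromosome segment, AUTS2 and ALK still passed (exact hypergeometric p adjusted over the genes 0.00835 and 0.0206). HDAC9, MSI2, PRKCE and PRKCA did not (adjusted hypergeometric p 0.0508, 0.235, 0.147 and 0.163). In the list where it had not passed, HDAC9 had 3 peaks over Naive where 3.09 were predicted by its segment. Likewise ALK had 4 over BDNF where 2.40 were predicted, and AUTS2 11 over Naive where 4.23 were predicted (exact hypergeometric p adjusted over the genes 1, 1 and 0.265).

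The comparison of BDNF with Naive asked what differentiation alone did, and rests on the libraries, since no pooled list of it was used here. In 3 regions all Naive and no BDNF libraries had a peak. They included a region inside NMNAT2, an NAD-synthesising enzyme of axons (chromosome 1, 183336684 to 183337117), and one on chromosome 7 from 54290281 to 54290565, outside any annotated gene and 252 kb from VSTM2A. No region had peaks in all BDNF and no Naive libraries. OR13G1 had a gene-end peak in all BDNF and no Naive libraries, but these peaks did not lie in a common region. The chromosome 7 region was also without a peak in every BDNF+Dox library, while that in NMNAT2 had one in 1 of 3. Other splits of the 6 libraries gave up to 5 regions, and 10 splits are too few to show a difference. With equal peak numbers per library 1 region was left, and at a −log10 p of 5 or more 0.

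Peak numbers of the groups did not differ beyond the spread between libraries at the authors' threshold. Libraries held 8674 ± 3221 (SD, n = 3) peaks in Naive, 5865 ± 1205 in BDNF and 8045 ± 2460 in BDNF+Dox, and the peaks covered 1707 ± 566.2, 1137 ± 270.6 and 1609 ± 597.6 kb. The BDNF+Dox to BDNF ratio of geometric means was 1.35 for peak number (exact two-sided permutation p = 0.354 over the 3 groups, n = 3 each) and 1.38 for covered length (exact permutation p = 0.386). At q of 0.05 or less, libraries held 16 to 58 peaks, 0.147 to 0.556% of their lists. That number did not differ between groups (exact permutation p = 0.136 over the 3 groups). At −log10 q of 3 or more the BDNF libraries held 1 to 8 peaks, the BDNF+Dox libraries 7 to 8 and the Naive libraries 8 to 11. The ratios of BDNF+Dox to BDNF were then 2.24 for number and 2.16 for length (exact permutation p of this pair 0.4 and 0.3, and over the 3 groups 0.0786 and 0.0429), and 1.21 and 1.23 without BDNF replicate 3, which had 1 peak. Gene ends of protein-coding genes held 2.67 ± 0.265%, 2.80 ± 0.229% and 2.95 ± 0.17% of peaks in Naive, BDNF and BDNF+Dox (exact permutation p = 0.368). Gene bodies, a measure added after seeing the data, held 37.7 ± 1.19%, 39.4 ± 1.99% and 42.4 ± 1.77% (exact permutation p = 0.0393, adjusted over the 4 measures 0.157), a difference that did not pass correction. Leaving out any Naive library, BDNF replicate 2, or BDNF+Dox replicate 2 or 3 took its unadjusted p to between 0.05 and 0.143. At −log10 p of 5 or more the difference between BDNF+Dox and BDNF was 1.78 percentage points in place of 3.01, and the exact permutation p over the 3 groups was 0.161.

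**Figure D2:**
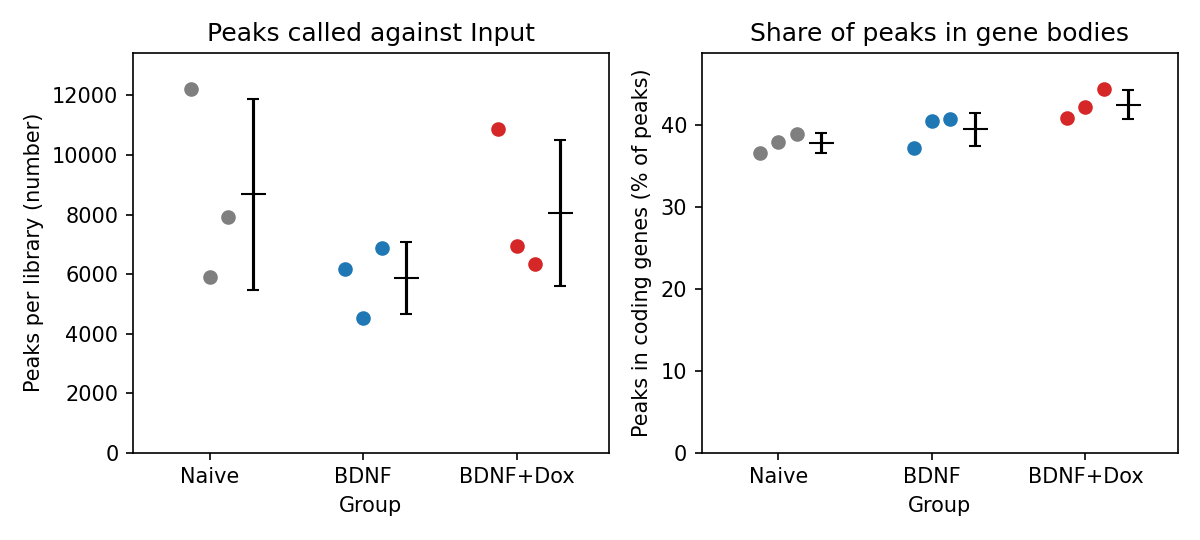
Peaks per library called against Input (left, number) and share of peaks in protein-coding gene bodies (right, % of peaks) for the 3 groups, with 1 point per library and the mean ± SD of 3 libraries beside the points. Peak numbers of the groups overlap, and gene body shares run from 36.5 to 38.9% in Naive, 37.1 to 40.7% in BDNF and 40.8 to 44.3% in BDNF+Dox.

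Gene lists at gene ends did not separate the groups either. For protocadherins, 1.33 ± 0.577 genes per Naive library, 0.333 ± 0.577 per BDNF and 6 ± 8.72 per BDNF+Dox library had a gene-end peak (SD, n = 3), and 16 of those genes came from BDNF+Dox replicate 2 alone (exact permutation p = 0.357). Means of the other 17 lists, adhesion, synaptic, axon, BAF, Parkinson and histone genes included, lay between 0 and 1 gene per library, and no list had an adjusted exact permutation p below 1. With gene bodies counted instead, an addition made after seeing the data, axon and cytoskeleton genes with a peak numbered 4.67 ± 0.577 per Naive, 2 ± 1 per BDNF and 7 ± 3 per BDNF+Dox library (exact permutation p = 0.0286, adjusted over the lists 0.514). Across all libraries the most frequent gene end was that of GABRA4, a GABA-A receptor subunit gene, with a peak in 4 libraries, and no gene end had one in all 9.

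Replicates shared few peaks. Pairs of libraries of a group had between 20 and 87 peaks in common, a mean of 0.779% of the smaller list, and 64074 of the 65632 merged regions (97.6%) were seen in only 1 library. The most frequent region, from 10732407 to 10733092 of chromosome 22 and outside any annotated gene, was seen in 7 libraries. The mean Jaccard index (shared over joint base pairs) was 0.237% within groups and 0.253% between groups, so peak sets did not follow the groups (difference −0.0163 percentage points, exact one-sided permutation p = 0.839 over 280 partitions). Shared peaks were nonetheless a median of 6.01 times as many as random placement gave within groups and 6.20 times as many between groups. Random placement allows neither for the Input that all 9 libraries share nor for sequence that is harder to map. The excess alone therefore does not show real peaks.

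**Figure D3:**
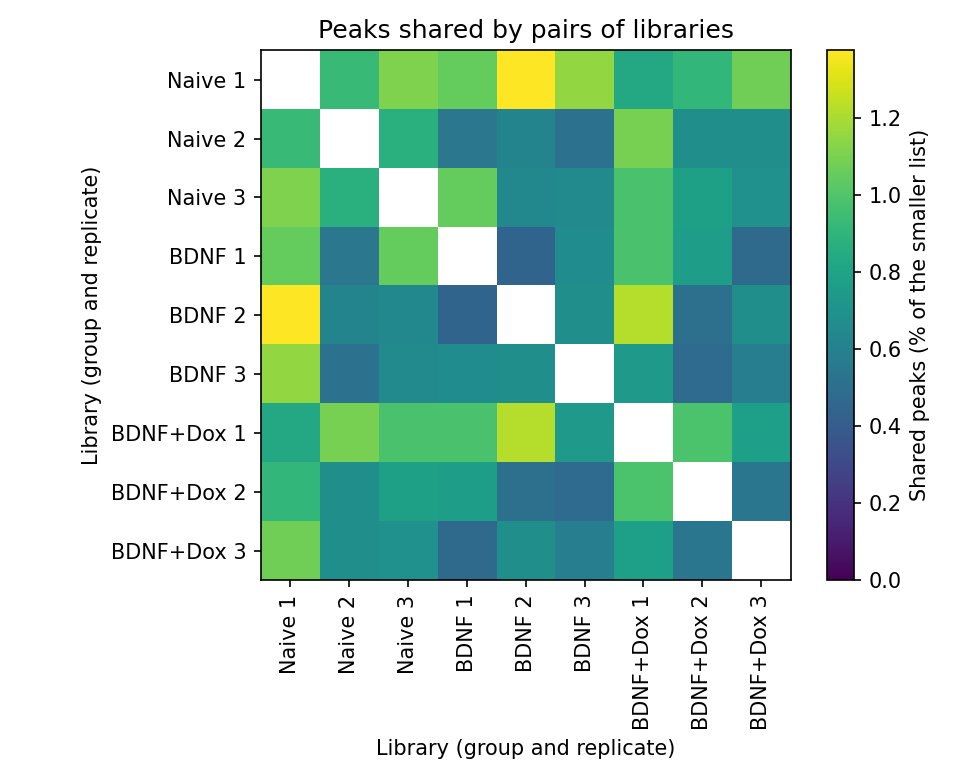
Peaks shared by each pair of libraries as a percentage of the smaller list (color scale, %), with the 9 libraries on both axes in group order. Pairs within a group (0.444 to 1.11%) and between groups (0.475 to 1.38%) cover similar ranges.

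Regions of the pooled lists were, by construction, occupied mainly in the libraries they were called from. Of the regions over BDNF, 6.21 ± 1.21% (SD, n = 3) overlapped a peak in a BDNF+Dox library, 0.0101 ± 0.0101% in a BDNF library and 0.317 ± 0.12% in a Naive library (exact permutation p = 0.00357, the smallest that 3 groups of 3 can give). Naive libraries played no part in choosing these regions and met them 2.09 to 2.81 times as often as random placement. Regions over Naive overlapped 6.31 ± 1.2% in BDNF+Dox, 0.223 ± 0.103% in BDNF and 0.00842 ± 0.00729% in Naive libraries (exact permutation p = 0.00357), and BDNF libraries met them 1.79 to 3.76 times as often as random placement. Peak lists of libraries from different groups shared 4.64 to 8.55 times as many peaks as random placement. The lower ratios for the pooled regions are therefore no evidence for those regions.

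Gene ends of protein-coding genes held fewer pooled peaks over BDNF than random placement at the authors' threshold. Of that list, 3.51% of peaks lay within 2 kb of an end of a protein-coding gene, against 4.77% with random placement on the same chromosome (two-sided permutation p = 0.002, the smallest that 1000 placements can give), and 47.1% lay in or near such a gene against 45.7% (p = 0.006). The gene-end ratio to random placement, 0.736 here, was 0.984 at q of 0.05 or less (permutation p = 1) and 0.957 at −log10 p of 5 or more (p = 0.791). Library peaks against Input lay at gene ends less often than these pooled peaks, in 2.41 to 3.11% of cases. Placement kept the chromosome but not the local sequence, so uneven coverage of gene ends was not separated from the mark. Over Naive, 4.43% lay at gene ends against 4.82% (permutation p = 0.0899) and 49.4% in or near a gene against 45.9% (p = 0.002). Among the 81 peaks over BDNF with q of 0.05 or less, a threshold added after seeing the data, 29.6% lay in or near a coding gene against 46.0% (permutation p = 0.002), the opposite direction.

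Chromosome 7, which carries NRCAM, SND1, AUTS2 and CNTNAP2, held 1.84 times its share of usable length in peaks over BDNF and 1.75 times in peaks over Naive (permutation p = 0.0001 for the highest ratio of any chromosome, the smallest that 10000 permutations can give). This ratio was already high in libraries against Input, at 1.58 ± 0.225 (SD, n = 3) in Naive, 1.63 ± 0.288 in BDNF and 1.57 ± 0.24 in BDNF+Dox (exact permutation p = 0.954), and so did not differ between groups. Chromosome arms, parted after the chromosome values were seen, differed as strongly. AUTS2, HDAC9, MSI2, ALK, PRKCA and PRKCE were left out of all arm values, whereas the chromosome 7 ratios use all peaks. Over BDNF, 1q held 2.08 and 1p 0.853 times its length share of peaks, 2p 1.59 and 2q 0.969, and 17q 1.40 and 17p 0.32. Over Naive, with the same genes left out, the ratios were 2.11 and 0.928, 1.64 and 1.04, and 1.47 and 0.336 for the same pairs. Library peaks against Input had 1.51 and 0.786 on 1q and 1p, 1.24 and 1.02 on 2p and 2q, and 0.885 and 0.465 on 17q and 17p. On 17q single libraries ranged from 0.752 to 1.1, below both pooled lists. Chromosome X had a ratio of 0.738 over BDNF and 0.729 over Naive, with 1.30 ± 0.181, 1.18 ± 0.222 and 0.925 ± 0.145 in the Naive, BDNF and BDNF+Dox libraries (exact permutation p = 0.104). The lowest pooled ratios were those of chromosomes 22 (0.236 over BDNF and 0.239 over Naive) and 19 (0.305 and 0.355). Every library also held fewer peaks on them than their length share.

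**Figure D4:**
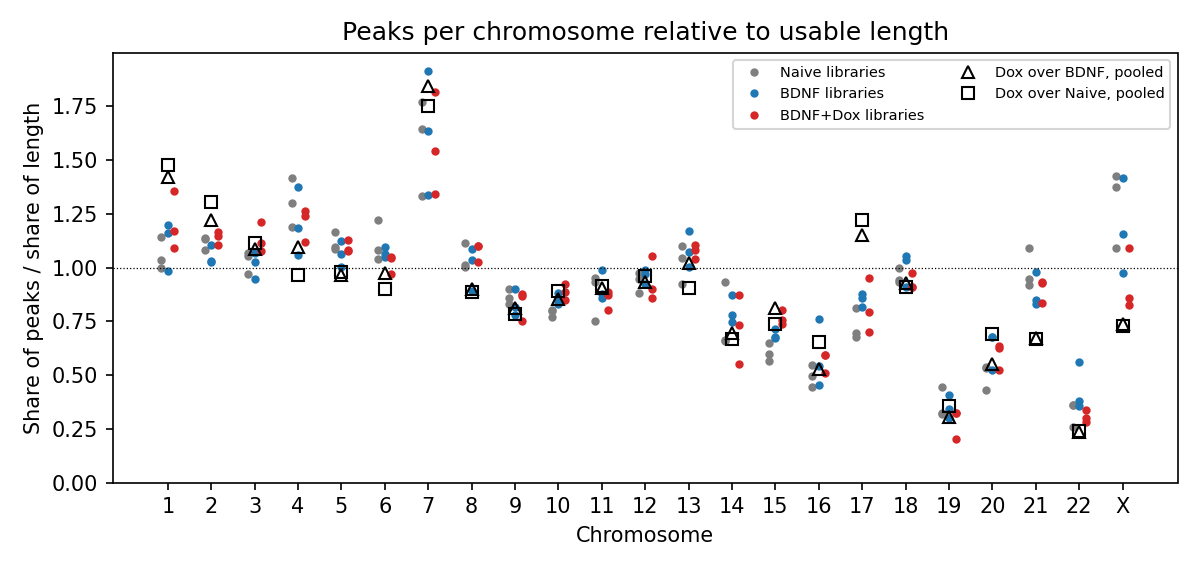
Share of peaks divided by share of usable length (vertical axis, ratio) for chromosomes 1 to 22 and X (horizontal axis), with 1 point per library and open symbols for the pooled lists. Chromosome 7 lies above 1.3 in all 9 libraries and both pooled lists.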

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

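Both mitochondrial tests, the comparison with random coincidence and the test within chromosome segments were chosen only after the results they measure were seen, while the test of the strongest library peaks and those of wider regions and of the library share were not. A condition on spread was, however, added to the library share test after its value was seen.

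Mitochondrial DNA lay outside the comparisons and carried signal: 11 narrow peaks over BDNF and 11 over Naive, including 7 and 10 of the 10 strongest peaks by q in those lists of the authors' deposited table. Peaks covered 68.3% and 75.8% of the annotated mitochondrial span, and folds reached 2.56 and 3.16 in the authors' deposited table. Mitochondrial DNA has no histones, and coverage of 68.3% or more of its span is consistent with more mitochondrial DNA overall in the merged BDNF+Dox libraries, a technical or cellular difference rather than a site of the mark. Against Input, 0 of the 3 BDNF+Dox libraries had a mitochondrial peak, so enrichment over Input on mitochondrial DNA after induction cannot be told apart from a difference below the detection of single libraries. Unplaced contigs, also outside the comparisons, had 3 peaks over BDNF and 4 over Naive with q of 0.05 or less in the authors' deposited table, and were not weighed further.

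Few peaks were shared between replicate libraries. Among the 10% of peaks with the largest −log10 p, a median of 2.59% overlapped a peak of another library of the group, against 1.30% of all peaks, which is consistent with sampling noise among calls at the loose p threshold. Simulated libraries without any real peak gave 3080 calls, against 4536 to 12207 found, so it stays open whether most calls are noise. Pairs within groups shared a median of 6.01 times as many peaks as random placement, which argues against random coincidence of evenly scattered peaks as the whole account. Random placement does not allow for the shared Input or for sequence that is harder to map. Simulated libraries with a shared Input had 0 calls in common. With a mean of 308 calls each in the simulated stretch, before scaling up, these were too few to measure such sharing. No biological explanation was tested for this pattern.

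In 6 genes the pooled lists held more peaks than the library peaks predicted, AUTS2, HDAC9 and MSI2 over BDNF and ALK, PRKCA and PRKCE over Naive, and none of them passed in both lists. All 6 lie on 7, 2p or 17q, which with 1q are known to be present in extra copies in the line, and each of these 4 segments held more pooled peaks than its library peaks predicted, the 6 genes left out (1.32 times on 1q, 1.24 on 2p, 1.11 on 7 and 1.47 on 17q over BDNF, and 1.34, 1.28, 1.08 and 1.55 over Naive), while the arms without known gains had 1.07 and 1.16 (1p), 0.956 and 1.02 (2q) and 0.717 and 0.745 (17p), so that chromosome 7 does not stand apart from 1p. Against the peaks of their own segment 2 genes stayed past the threshold, AUTS2 (ratio 3.31 before and 2.91 after, adjusted hypergeometric p 0.00835) and ALK (4.98 and 3.74, 0.0206). Extra copies of 1q, 2p, 7 and 17q as whole segments may thus be part of the account but are not the account of all 6. In simulations 1.5 times the coverage raised pooled calls 1.68 times and library calls 1.47 times. Because the test predicts from the mean of a segment, a gain of only part of it was not excluded for AUTS2 and ALK. The predicted number rose, and the call ended, for HDAC9 (3.13 and 2.76, 0.0508, a narrow miss), MSI2 (4.82 and 3.17, 0.235), PRKCE (4.54 and 3.41, 0.147) and PRKCA (4.24 and 2.61, 0.163), in which an excess beyond the segment is neither shown nor excluded. A gain of the wider chromosome region (median ratio within 5 Mb of 1.48, from 0.924 to 1.59) and more of the mark in these genes after induction cannot be told apart. The genes held 0.152 ± 0.0879% of library peaks in BDNF+Dox, 0.175 ± 0.0551% in BDNF and 0.105 ± 0.017% in Naive (SD, n = 3, exact permutation p = 0.496 over the 3 groups). By the rule set beforehand, a mean in BDNF+Dox at or below that in BDNF counted against more of the mark. The means met that rule, but by less than their spread, and the BDNF+Dox share lay above that in Naive. The condition on spread was added after the value was seen, and without it the result counted against more of the mark.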

How the results depend on the processing

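Thresholds of −log10 p of 5 and q of 0.05, all settings of the gene body share, and leaving out libraries at −log10 q of 3 were chosen only after the data were seen. Among the main results 164 alternatives left direction and call as they were, and 63 moved, 18 weakened, 7 strengthened and 8 reversed a value; the cause was not tested unless stated. At −log10 q of 3 or more, the ratios of BDNF+Dox to BDNF were 2.24 for peak number and 2.16 for covered length (exact permutation p over the 3 groups 0.0786 and 0.0429, of this pair 0.4 and 0.3), replicate overlap was −5.93 percentage points, library peaks in pooled regions differed by 0.0101 and 0.00421 percentage points, all region counts were 0, 8 and 10 pooled peaks were left, their gene-end ratios to random were 0 and 2.36 and their coding gene ratios 0.801 and 1.11, 0 lists passed over BDNF, and the highest chromosome ratios were 8.64 and 6.91. There the ratios rested on BDNF replicate 3, with 1 peak, without which they were 1.21 and 1.23, while they were 3.42 and 3.23 without BDNF replicate 1 and 2.71 and 2.54 without BDNF replicate 2. The p over the 3 groups passed 0.05 for number only without BDNF replicate 1 (exact permutation p = 0.0107), and for length it did not pass without any single Naive or BDNF+Dox library (exact permutation p from 0.0607 to 0.139). Gene body share gave no value there. At q of 0.05 or less, 81 and 80 peaks had gene-end ratios of 0.984 and 1.001 and coding gene ratios of 0.644 and 1.04. At −log10 p of 5 or more, the gene body difference was 1.78 and its unadjusted p was no longer under 0.05 (exact permutation p = 0.161). There replicate overlap was −0.0485, region counts were 0, 1164 and 934 peaks had gene-end ratios of 0.957 and 1.18, the coding gene ratio over BDNF was 1.05, and 2 lists passed over Naive. With 5 kb windows the gene-end difference between BDNF+Dox and BDNF was 0.0447 (exact permutation p of this pair 0.8), and the p over the 3 groups of 0.0464 went with a lower share in Naive (6.4, 6.91 and 6.96% in Naive, BDNF and BDNF+Dox). With equal peak numbers, Dox-only, Dox-gained and Dox-over-Naive regions were 0, and Naive-only and BDNF-lost regions 1. Widening peaks by 500 bp gave 6 Dox-only, 6 Naive-only, 2 BDNF-only, 6 Dox-gained, 2 Dox-lost, 3 BDNF-gained, 6 BDNF-lost and 6 Dox-over-Naive regions, by construction. Broad lists held 25226 and 20165 peaks, with a gene-end ratio of 0.854 over Naive (permutation p = 0.002, the smallest possible). In 2 or more BDNF+Dox libraries, 57 and 41 peaks were left, with a gene-end ratio of 0.729 and a coding gene ratio of 0.911 over BDNF, a coding gene ratio of 0.980 over Naive, and 0 lists over BDNF. Over BDNF, 0 lists passed at gene ends only and 8 without length matching, and 4 over Naive. Leaving out 1 library gave 2 to 56 Dox-only, 2 to 75 Naive-only, 0 to 31 BDNF-only, 2 to 62 Dox-gained, 0 to 33 Dox-lost, 0 to 37 BDNF-gained, 3 to 79 BDNF-lost and 2 to 59 Dox-over-Naive regions, higher whenever a library of the required group was left out, since fewer libraries are then required. The gene body difference ranged from 1.86 to 3.82. Its unadjusted p was no longer under 0.05 without Naive replicate 1, 2 or 3, BDNF replicate 2, or BDNF+Dox replicate 2 or 3 (exact permutation p from 0.05 to 0.143). Replicate overlap ranged from −0.0290 to 0.00188 and reversed without BDNF replicate 1. Same-numbered replicates showed no common direction (correlations of their deviations from −0.856 to 0.628). These correlations were not tested, so a pairing of samples by number is neither shown nor excluded. Permutation within numbers changed no call. The peak lists hold no counts per region, so what depth limits was not tested.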

Other observations

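The comparison of AUTS2 and ALK with their segments, the hypergeometric tests of gene lists and the relation to fragment length were chosen only after the results were seen, and the counts over other splits of the libraries were not.

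NRCAM, a neuronal adhesion gene, had an H4R3me2s peak in all 3 BDNF+Dox libraries and in none of the others, at the place of its strongest peak in both pooled comparisons. Both pooled lists contain the reads of these same libraries, so the pooled peak is no independent evidence. L1CAM, a relative of NRCAM, had no peak in any library or pooled list, but it is a much shorter gene and catches few by chance. A candidate explanation is a local gain of the mark in NRCAM, but regions of this kind were not more frequent than in other groupings. For regions in all BDNF+Dox and no other library, 20 of the 84 choices of 3 libraries gave as many as the 2 found (highest other 5). Chance cannot be excluded there, nor for the 2 Naive-only regions (20 of 84, highest other 5). For the 0 BDNF-only regions the comparison decides nothing, since all 84 choices must give as many (highest other 5).

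With 6 libraries, 10 splits are too few for a share under 0.05. Dox-gained regions numbered 2 (highest other 3, as many in 6 splits), Dox-lost 0 (3, 10 splits), BDNF-gained 0 (5, 10 splits), BDNF-lost, that in NMNAT2 included, 3 (5, 3 splits), and Dox-over-Naive gained 2 (4, 7 splits). Every split must match a count of 0, so for Dox-lost and BDNF-gained regions the splits decide nothing.

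Noradrenergic markers held 16 distinct pooled peaks over Naive where library peaks predicted 3.88 (exact two-sided hypergeometric p adjusted over the 18 lists 1.11e-05), and 10 against 3.96 over BDNF (adjusted 0.142). ALK, a receptor kinase gene of neuroblastoma on 2p, held 14 of the 16 within its body and 2 kb on each side, so the list result is that of 1 gene.

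The chromosome 7 ratio of the 9 libraries fell with fragment length (Pearson r = −0.884, exact permutation p = 0.00368, adjusted over 4 relations 0.0147; Spearman rho = −0.917, p = 0.00131, adjusted 0.00525). It was −0.788 without the 2 libraries farthest from the median fragment length and −0.883 after centring on the groups. The other 3 relations, chromosome X ratio with fragment length and peak number with reads and with fragment length, had r of 0.478, 0.498 and 0.0645 (exact permutation p = 0.185, 0.186 and 0.858) and rho of 0.417, 0.35 and 0.117 (exact permutation p = 0.270, 0.359 and 0.776). Without the 2 farthest libraries their r was 0.0635, −0.286 and 0.190, and after centring on the groups 0.790, 0.432 and 0.00603, so the chromosome X relation differed with the choice of libraries and centring.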
